A study of Mus musculus with 15 samples.

How the data were processed

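RNA of 15 samples of mouse splenic B cells had been measured on exon and junction arrays, 1 array per sample. The deposited table holds log2 SST RMA values from the Affymetrix Expression Console, per the labels (SST is a signal space transformation, which stretches folds), with versions not given in the sources used here. By this account the authors' software corrected background, normalized between arrays and summarised probes, and the values were used as deposited. They ran from 1.74 to 19.93, and values near the upper end are compressed, so folds are those of this transformed scale. The table has 725678 rows: 437027 exon regions, 282044 junctions and 6607 control or other rows. All 15 sample columns were matched to the labels and 0 were left unmatched. No pair of arrays was a duplicate: between 6 and 127 rows were identical in a pair, and Pearson's r over all rows lay between 0.907 and 0.987.

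The annotation of the rows gave 1 gene symbol for 580167 rows, several for 18694 and none for 126817, and rows of the last 2 kinds were left out of gene values. Symbols were compared with current RefSeq symbols: 1463 were updated through synonyms, and 31211 of 31366 genes are found among current symbols. The value of a gene is the median of the log2 values of its exon regions (338822 rows, a median of 6 per gene, and 1 for 7644 genes). Junction rows (241345) entered only the tests within genes. Listed genes without an exon region of their own were not analysed here.

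The groups, comparisons, tests, gene lists and naming rule were chosen before the data were examined. A limma model with a mean for each of the 4 groups was fitted to all 15 arrays, with 5 contrasts: LPS against no LPS in each genotype, ELL2 cko against WT without and with LPS, and the difference of the 2 LPS changes. Moderated tests (eBayes) were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all 31366 genes, with calls at an adjusted p under 0.05. SE is the standard error of a log2 change from this model, which shares one spread per gene between the groups. Sharing it assumes an equal spread in groups that differ in it where other cells are present in some arrays. No filter on level was used for genes.

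The 32 gene lists were tested with limma's camera on the moderated statistics with a preset correlation of 0.01, adjusted over 160 tests of lists and contrasts, and again with an estimated correlation. Of the 160 tests 71 were called with the preset and 0 with the estimated correlation (lowest adjusted p = 0.0784). The preset value is low for genes that vary together between arrays, so both are given beside the called lists that are described. Counts adjusted over the list alone use the p-values of its members only. Marker lists of other cells were tested in the same way: 7 of the 19 T cell markers, 1 of the 13 NK cell markers, 8 of the 20 monocyte and macrophage markers and 3 of the 16 neutrophil markers lay above the median gene of WT cells without LPS (5.06).

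Unequal change of rows within a gene was tested with diffSplice of limma and a Simes p per gene. Kept were genes with at least 3 rows whose value reached the median of all genes in every group of the contrast, and rows whose mean reached the 25th percentile. Added after seeing the data, the splicing index is the value of a row minus the median of its gene in that array, tested with limma for each row and a Simes p per gene. Row positions were not used here, so no exon is given a number.

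Named in every comparison were Ell2, the immunoglobulin constant regions and Prdm1, Irf4, Xbp1, Pax5, Tnfrsf17 and Atf6. To these came the 8 largest called rises and the 8 largest called falls without overlap between groups, up to 3 members per list, and 6 genes for the difference of responses. Predicted genes and variable segments were left out of the largest changes. For tests within genes Ighm, Ell2, Ptprc and the 5 genes with the smallest adjusted p were eligible. A gene that meets the rule is given where it tells most about its group.

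The methods were tested on simulated data with 200 changed genes. Simulated genes and rows varied independently, each with the same spread in all arrays, and no array held RNA of other cells. The numbers of false calls given here thus need not hold for the real arrays. For LPS in WT, changes of 0.5, 1 and 2 log2 units were recovered in 5%, 60.5% and 95% of genes with 0, 2 and 14 false calls. For genotype with LPS 0%, 53.5% and 94.5% were recovered, with 1, 5 and 12 false calls. With changes of 2 log2 units in 200 genes, diffSplice recovered 83% for LPS in WT with 747 false calls and 72.5% for genotype with LPS with 843. The splicing index recovered 23% and 14% with 2 and 1.

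Alternatives were a filter on dim genes, a further quantile normalization, centring of arrays, eBayes with trend and robust settings, a size threshold, the mean of exon regions, only the 2 groups compared, each array left out in turn, and replicate number as a block. For tests within genes they were no filter, no junctions, an F test, a further quantile normalization, arrays left out and the block. Chosen after seeing the data were leaving out the 4 ELL2 cko arrays with markers of other cells, the mean of the T cell markers as a covariate, the sex of the mouse as a term, genes with rows that rise and rows that fall, and the splicing index. Sex was read from the level of Xist. R 4.3.3, limma 3.58.1, data.table (version 1.17.8), Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.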

Results

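The series asked how B cells lacking ELL2, a factor that helps RNA polymerase II elongate transcripts, differ in RNA levels and splicing when they are driven towards antibody secretion. B cells were purified on magnetic columns from the spleens of wild-type (WT) mice and of mice with a conditional knockout of ELL2 (ELL2 cko). RNA was taken directly after purification, or after 72 hours of culture with lipopolysaccharide (LPS), a bacterial cell wall component that makes B cells divide and become antibody-secreting cells. There were 15 arrays: 4 of WT and 4 of ELL2 cko cells without LPS, 4 of WT cells with LPS and 3 of ELL2 cko cells with LPS. Each array measured 437027 exon regions and 282044 exon junctions on a log2 scale. The median over all rows of an array lay between 5.72 and 5.78, and the median of the background control rows between 3.02 and 3.43. The number of arrays limits the precision of every comparison. No cells were cultured without LPS, so a change with LPS, as written here, covers both LPS and the 72 hours in culture, which cannot be separated. Per the labels the cells came from individual mice, and p-values measure the spread between arrays of a group. By the level of Xist, the RNA that silences an X chromosome in females, each WT group held 2 females and 2 males, the unstimulated ELL2 cko group 3 females and 1 male, and the ELL2 cko LPS group 3 females.

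Ell2, the targeted gene, had log2 values of 11.07, 10.87, 11.08 and 11.10 in the WT arrays without LPS and 10.38, 9.78, 10.75 and 11.17 in the ELL2 cko arrays without LPS. With LPS the values were 16.86, 15.90, 16.56 and 15.73 in WT and 14.15, 14.16 and 14.14 in ELL2 cko. Ell2 rose by 5.23 ± 0.27 (log2 change ± SE, limma adjusted p = 1.49e-08, n = 4 and 4) with LPS in WT, and by 3.63 ± 0.29 (adjusted p = 7.87e-06, n = 4 and 3) in ELL2 cko. Between genotypes the gene value differed by -0.51 ± 0.27 (adjusted p = 0.62) without LPS and fell by 2.11 ± 0.29 (adjusted p = 9.03e-04) with LPS. The gene value is a median over exon regions, most of which need not lie in the deleted part, which the labels do not state. One exon region, PSR1300005919.mm.1, stood apart. Its values in ELL2 cko without LPS were 8.98, 7.96, 10.06 and 9.35, against 12.91 to 13.13 in WT. With LPS they were 11.38, 7.97 and 7.87, against 17.13 to 18.56 in WT. This region was lower by 8.75 with LPS (log2 difference -8.75, adjusted p = 3.69e-04) and differed by -3.93 (adjusted p = 0.268) without LPS. A junction row of the gene, JUC1300003129.mm.1, differed by -8.72 (adjusted p = 5.05e-05) with LPS and by -4.28 (adjusted p = 0.0924) without. In this region all 7 ELL2 cko arrays lay below every WT array of the same treatment.

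**Figure D1:**
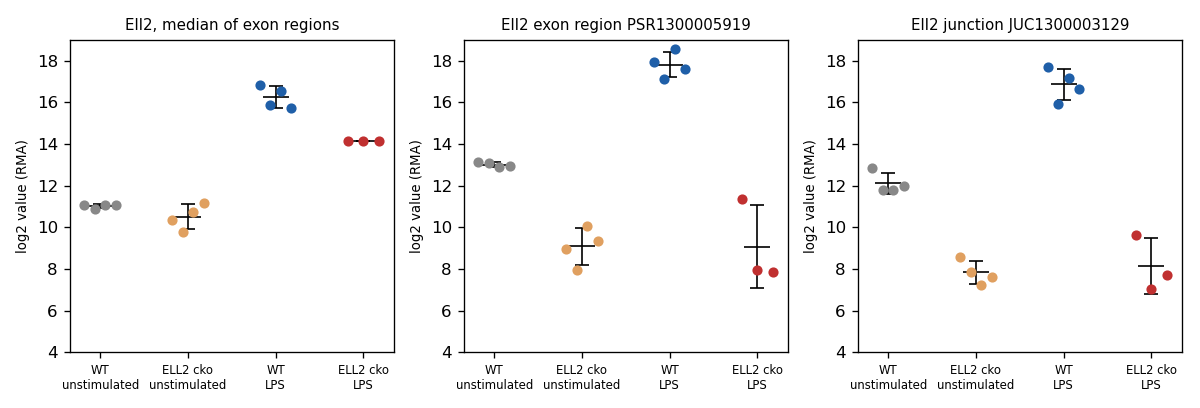
Ell2 gene value (log2, median of its exon regions) and log2 values of the exon region and the junction that differed most between genotypes, for each of the 15 arrays by group; points are arrays and bars are group means with SD. The exon region lies between 7.87 and 11.38 in ELL2 cko arrays and between 12.91 and 18.56 in WT arrays.

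After 72 hours of culture with LPS, WT cells had higher levels of genes of antibody secretion and division and lower levels of those of the resting B cell. Prdm1, which encodes the transcription factor Blimp-1 that antibody-secreting cells require, rose by 6.79 ± 0.31 (log2 change ± SE, n = 4 and 4). Xbp1, a transcription factor of the unfolded protein response and of secretory cells, rose by 6.70 ± 0.25, and Irf4, which acts with Blimp-1 in plasma cell formation, by 3.84 ± 0.30. Slpi, a secreted protease inhibitor, rose by 9.57 ± 0.82, and the endoplasmic reticulum (ER) folding factor Fkbp11 by 8.66 ± 0.49. Without LPS, Fkbp11 (4.75 to 5.45), Slpi (5.38 to 6.23) and Ctla4, Sec24d and Cdk1, given below, lay near the median gene of WT cells (5.06). They were not shown to be expressed, so their changes are read as lower limits and not ranked. Fcmr, the receptor for IgM, fell by 7.42 ± 0.88, and Fcer2a, the IgE receptor CD23 of mature B cells, by 6.82 ± 1.01. Their values in the WT LPS arrays were 7.39, 11.09, 9.24 and 11.69 for Fcmr and 5.86, 9.98, 7.26 and 12.29 for Fcer2a, so the size of these falls depends on the array. Further large rises were those of Derl3 (8.21), which takes part in ER-associated degradation, Fdps (7.31), an enzyme of sterol and isoprenoid synthesis, the ER peroxiredoxin Prdx4 (6.91), the ER stress protein Creld2 (6.85) and the inhibitory receptor Ctla4 (6.80). Further large falls were those of Icosl (-6.55), the ligand of the T cell costimulator ICOS, Sorl1 (-6.16), the complement receptor Cr2 (-5.86), the complement regulator Cd55 (-5.72), Tlr1 (-5.64) and the urokinase receptor Plaur (-5.58). Of the immunoglobulin constant regions, Ighd fell by 6.89 ± 0.86, and Ighg2b (5.11 ± 0.69) and Ighg3 (3.19 ± 0.49) rose. Ighm changed by 0.18 ± 0.10 (adjusted p = 0.231), with all arrays between 19.38 and 19.85, close to the highest value in the table, 19.93. Pax5, the factor that maintains B cell identity, fell by 3.71 ± 0.73, while Atf6 (3.11 ± 0.31) and Tnfrsf17 (1.20 ± 0.21), the receptor BCMA, rose.

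By gene group, 27 of 31 measured members of the antibody-secreting cell list rose and 1 fell (29 called adjusted over the list alone). The median log2 change was 3.83 (camera adjusted p = 1.09e-54, adjusted p = 0.101 with an estimated correlation). Of 39 unfolded protein response genes 32 rose and none fell (33 over the list alone). Their median was 3.39 (adjusted p = 2.78e-55, adjusted p = 0.0786 with an estimated correlation). Of 46 genes of ER translocation and secretion 42 rose (42 over the list alone). This group had a median of 2.45 (adjusted p = 5.67e-34, adjusted p = 0.186 with an estimated correlation). Examples are Sec24d (6.09), a coat protein of vesicles leaving the ER, and Ssr3 (4.86), a subunit of the translocon-associated complex. Of 41 cell cycle genes 38 rose (39 over the list alone), among them Mki67 (5.04) and Cdk1 (4.91). The cell cycle median was 2.97 (adjusted p = 3.63e-35, adjusted p = 0.186 with an estimated correlation). Of 32 mature B cell identity genes 29 fell (31 over the list alone). Their median was -3.24 (adjusted p = 7.94e-27, adjusted p = 0.186 with an estimated correlation). Of 14 genes of MHC class II presentation 10 fell and 1 rose (13 over the list alone), among the falls H2-Oa (-5.51) and the class II transactivator Ciita (-5.18). This list had a median of -2.80 (adjusted p = 5.41e-07, adjusted p = 0.365 with an estimated correlation). Glycolysis genes rose in 11 of 19 cases and fell in 1 (12 over the list alone, median 1.03, adjusted p = 7.36e-05, adjusted p = 0.428 with an estimated correlation). Oxidative phosphorylation genes rose in 22 of 38 cases and fell in 3 (26 over the list alone, median 0.88, adjusted p = 4.39e-07, adjusted p = 0.334 with an estimated correlation). Interferon response genes rose in 15 of 29 cases (16 over the list alone, median 1.07, adjusted p = 1.3e-07, adjusted p = 0.339 with an estimated correlation), led by Bst2 (5.48) and Isg20 (4.01). Replication-dependent histone genes rose in 22 of 35 cases (25 over the list alone, median 1.59, adjusted p = 3.94e-08, adjusted p = 0.109 with an estimated correlation). Quiescence genes fell in 7 of 20 cases and rose in 2 (11 over the list alone, median -0.55, adjusted p = 0.0105, adjusted p = 0.399 with an estimated correlation), with falls in Btg1 (-4.73) and Klf2 (-2.40). Splicing regulators of the SR and hnRNP families fell in 19 of 54 cases and rose in 8 (31 over the list alone, median -0.36, adjusted p = 0.0048, adjusted p = 0.191 with an estimated correlation), with Clk1 (-1.78) lower and Mbnl2 (3.06) and Srsf9 (2.25) higher. Markers of T, NK, monocyte and neutrophil cells had medians of -0.14, -0.19, -0.24 and 0.03 and were not called (adjusted p = 0.564, 0.693, 0.642 and 0.785).

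In all, 7671 of 31366 genes were called by limma in WT, 4350 higher and 3321 lower, and 4114 of them changed by at least 1 log2 unit. The share of higher genes was 56.7%, and 45.7% of 7914 called genes after a further quantile normalization. Of 92 named genes called, 84 kept their call with any 1 array left out.

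In ELL2 cko cells genes of secretion and division also rose with LPS. Prdm1 rose by 4.71 ± 0.34 (log2 change ± SE, n = 4 and 3), Xbp1 by 4.07 ± 0.27, Irf4 by 2.60 ± 0.33 and Atf6 by 2.38 ± 0.34. Over all arrays the rises included those of Saa3 (7.64 ± 0.85), an acute phase protein, the transcription factor Zbtb32 (7.40 ± 0.98), Fdps (5.63 ± 0.34), Slpi (5.19 ± 0.89), the inhibitory receptor Tigit of T and NK cells (5.08 ± 0.57), the glycolytic enzyme Aldoc (4.90 ± 0.68) and the sterol regulator Insig1 (4.67 ± 0.57). Icosl fell by 4.93 ± 0.49, Cd55 by 3.99 ± 0.42, Plaur by 3.89 ± 0.50, the bactericidal protein gene Pglyrp1 by 4.08 ± 0.47, Xkrx by 3.98 ± 0.44, Rgs2, a regulator of G protein signalling, by 4.98 ± 0.97 (values of 13.97, 12.97, 9.50 and 9.38 in ELL2 cko replicates 1 to 4 without LPS, the first 2 of which held markers of other cells) and Adgre5 by 3.63 ± 0.35. Fcer2a fell by 4.18 ± 1.09, a call (adjusted p = 0.025) that was lost on leaving out ELL2 cko LPS replicate 1, 2 or 3 or unstimulated replicate 3 or 4 (adjusted p up to 0.0828). Ighg3 rose by 3.59 ± 0.53. Ighg2b (2.28 ± 0.75, adjusted p = 0.0704), Ighd (-2.43 ± 0.93, adjusted p = 0.122), Ighm (0.30 ± 0.11, adjusted p = 0.091) and Pax5 (-0.83 ± 0.79, adjusted p = 0.601) were not called. Without LPS, Saa3 and Aldoc lay near the median gene, as did Pglyrp1 and Xkrx with LPS, so their changes are read as lower limits. With 1 ELL2 cko LPS array (replicate 1) and unstimulated replicates 3 and 4 left, the arrays without a high T cell marker mean, the rises were 6.41 for Saa3, 8.74 for Zbtb32, 7.50 for Slpi, 3.81 for Tigit, 6.20 for Aldoc, 3.71 for Insig1 and 5.53 for Prdm1. The falls were then -6.17 for Icosl, -5.37 for Plaur, -5.46 for Xkrx, -5.15 for Fcer2a and -4.23 for Adgre5.

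Of the antibody-secreting cell list 16 of 31 members rose (21 over the list alone), among them Derl3 (4.62) and Mzb1 (4.36), an ER chaperone partner of B cells. The median log2 change was 1.19 (camera adjusted p = 5.36e-22, adjusted p = 0.191 with an estimated correlation). Of the unfolded protein response genes 25 of 39 rose (32 over the list alone, median 1.42, adjusted p = 1.71e-23, adjusted p = 0.165 with an estimated correlation), and of the ER secretion genes 14 of 46 (22 over the list alone, median 0.78, adjusted p = 1.52e-09, adjusted p = 0.386 with an estimated correlation). Cell cycle genes rose in 37 of 41 cases (40 over the list alone, median 1.89, adjusted p = 2.79e-29, adjusted p = 0.186 with an estimated correlation), with Nusap1 (3.18) as an example. Interferon response genes rose in 19 of 29 cases (25 over the list alone, median 1.74, adjusted p = 1.65e-19, adjusted p = 0.165 with an estimated correlation), among them the RNA sensor Ifih1 (3.16) and Usp18 (4.27). The interferon list mean was 9.20, 10.24 and 10.31 in ELL2 cko LPS replicates 1 to 3, and with only replicate 1 of these and unstimulated replicates 3 and 4 left, 4 of 29 members were called and the median was 0.93. Mature B cell identity genes fell in 10 of 32 cases (10 over the list alone, median -0.81, adjusted p = 1.2e-09, adjusted p = 0.428 with an estimated correlation). With the same 3 arrays left, the medians of the antibody-secreting, mature B cell and quiescence lists were 1.88, -1.61 and -0.49, and the changes of Rgs2 and Usp18 -2.89 and 2.69. Quiescence genes fell in 7 of 20 cases (12 over the list alone, median -0.79, adjusted p = 1.68e-05, adjusted p = 0.186 with an estimated correlation). Glycolysis genes rose in 9 of 19 cases and fell in 1 (12 over the list alone, median 0.95, adjusted p = 1.54e-05, adjusted p = 0.399 with an estimated correlation). The glycolysis mean was 10.48, 9.20 and 9.27 in ELL2 cko LPS replicates 1 to 3, and Aldoc was 11.72, 9.52 and 9.85. The MHC class II list was not called (median -0.95, adjusted p = 0.175), with 1 member higher and 1 lower.

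Markers of other cells moved with LPS in ELL2 cko. The median change was -1.63 for T cell markers (camera adjusted p = 0.0036, adjusted p = 0.668 with an estimated correlation), -1.70 for NK cell (1.4e-04 and 0.494), -1.27 for monocyte and macrophage (3.46e-05 and 0.527) and -2.52 for neutrophil markers (7.84e-04 and 0.604). The T cell marker call was lost without ELL2 cko LPS replicate 1 or unstimulated replicate 1 or 2 (adjusted p up to 0.114). Of these lists 5 monocyte markers fell singly and no T cell, NK cell or neutrophil marker did, while 7276 of all genes had an unadjusted limma p under 0.05. The mean of the 19 T cell markers was 10.64, 10.20, 5.14 and 5.12 in the ELL2 cko arrays without LPS and 5.07, 6.70 and 6.88 in those with LPS, against 4.98 to 5.34 in the 8 WT arrays. Without the 4 ELL2 cko arrays whose T cell marker mean lay over 1 log2 unit above the WT unstimulated mean (unstimulated replicates 1 and 2, LPS replicates 2 and 3), an alternative chosen after seeing the data, the T cell, NK cell, monocyte and neutrophil medians were 0.01, -0.05, -0.49 and 0.20. Dendritic cell markers had a median of -0.79 over all arrays (camera adjusted p = 0.0048, 0.334 with an estimated correlation). Of these 12 markers 4 fell and 2 rose, and their median was -0.25 without the 4 arrays.

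In total 3246 genes were called in ELL2 cko, 1995 higher and 1251 lower. Without the 4 arrays with markers of other cells 1306 were called, 1015 of them also called with all arrays. That fit keeps 1 ELL2 cko array with LPS and 2 without, so the spread comes mostly from WT arrays, and a call lost in it says little. The count was 1943 without LPS replicate 2 and 1931 without LPS replicate 3, and 2156 when only the 2 groups compared were fitted. Of 82 named genes called, 61 kept their call with any 1 array left out and 46 without the 4 arrays.

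Without LPS, the genotypes differed most in markers of cells other than B cells, which were high in 2 of the 4 ELL2 cko arrays. S100a8, a calcium-binding protein of neutrophils, had values of 15.32, 14.91, 3.87 and 3.54 in ELL2 cko, against 3.18 to 4.20 in WT. The neutrophil granule protein gene Ngp had 15.95, 16.47, 4.42 and 4.29. Cd8a, a T cell coreceptor, had values of 9.38, 9.47, 4.89 and 5.81 in ELL2 cko, and C1qa, a complement gene of macrophages, 8.32, 8.48, 5.43 and 6.63. The group differences of these genes were 5.77 ± 2.15, 5.88 ± 2.24, 2.37 ± 0.79 and 2.09 ± 0.49 (log2 ± SE, n = 4 and 4). None passed the test (adjusted p = 0.478, 0.478, 0.452 and 0.301). By list, the median differences were 2.37 for T cell markers (camera adjusted p = 1.65e-12, adjusted p = 0.337 with an estimated correlation), 1.90 for NK cell markers (1.7e-11 and 0.331), 2.25 for monocyte and macrophage markers (1.74e-20 and 0.201), 2.64 for neutrophil markers (9.12e-12 and 0.337) and 0.64 for dendritic cell markers (4.12e-08 and 0.109). Adjusted over the list alone, 16 of 19 T cell, 13 of 13 NK cell, 16 of 20 monocyte, 14 of 16 neutrophil and 4 of 12 dendritic cell markers were called, and over all genes 0 were. The medians without the 4 arrays were -0.10, 0.08, 0.37, -0.09 and 0.26, and the monocyte and dendritic cell lists were still called there. The monocyte mean was 8.93, 8.87, 5.25 and 5.99 in ELL2 cko replicates 1 to 4, against 5.14 to 5.32 in WT.

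The mature B cell identity list was lower in ELL2 cko without LPS (median -0.64, camera adjusted p = 6.16e-07, adjusted p = 0.489 with an estimated correlation), with no member called over all genes or over the list alone. Its mean was 12.57, 12.59, 13.71 and 13.60 in ELL2 cko replicates 1 to 4, against 13.63 to 13.82 in WT, and without the 4 arrays the median was -0.09. The cell cycle list was higher (median 0.62, adjusted p = 3.51e-11, adjusted p = 0.386 with an estimated correlation), with 4 members called over the list alone, led by Pcna (0.79 ± 0.18) and Nusap1 (1.06 ± 0.27), and a median of 1.11 without the 4 arrays. Its mean was 7.43, 7.37, 8.58 and 8.45 in ELL2 cko replicates 1 to 4, against 7.19 to 7.75 in WT. Small nuclear RNA genes were higher (median 1.05, adjusted p = 9.11e-08, adjusted p = 0.337 with an estimated correlation), with 7 of 18 called over the list alone. Their mean was 11.03, 11.09, 8.91 and 8.92 in the ELL2 cko arrays, high in the same 2 arrays as the T cell markers, against 8.64 to 9.05 in WT. These genes have many near-identical copies, so the level of each one is uncertain. The list also holds small nucleolar RNA genes (Rnu3a, Rnu3b1, Rnu3b2, Rnu3b3 and Rnu3b4) and Y RNA genes (Rny1 and Rny3). The interferon response list had a median of 0.41 (adjusted p = 6.08e-06, adjusted p = 0.386 with an estimated correlation), with 1 member called over the list alone, Bst2 (1.60 ± 0.31) having the smallest p. The oxidative phosphorylation list was higher (median 0.19, camera adjusted p = 0.0012, 0.527 with an estimated correlation), with a median of 0.40 without the 4 arrays. The cleavage and polyadenylation list was lower (median -0.18, camera adjusted p = 0.0084, 0.386 with an estimated correlation), with a median of 0.04 without them. Of the immunoglobulin constant regions, whose list was not called (median 0.81, adjusted p = 0.115), Ighg2b differed by 3.12 ± 0.69 (adjusted p = 0.292), Ighg3 by 1.79 ± 0.49 (adjusted p = 0.392) and Igha by 2.61 ± 0.69 (adjusted p = 0.392). Igha was 11.04, 9.63, 7.61 and 7.52 in ELL2 cko replicates 1 to 4, and its difference was 1.23 without the 4 arrays. Prdm1 (0.11 ± 0.31), Xbp1 (-0.06 ± 0.25), Irf4 (-0.34 ± 0.30) and Pax5 (-0.68 ± 0.73) did not pass the test.

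Over all genes 4 were called without LPS, all higher in ELL2 cko, and 2829 had an unadjusted p under 0.05. Of these, 3 could be named: Txn1, the redox protein thioredoxin (1.41 ± 0.19, adjusted p = 0.0411), and the alpha tubulins Tuba1a (1.01 ± 0.14, adjusted p = 0.0411) and Tuba1c (0.87 ± 0.12, adjusted p = 0.043). The tubulins are near-identical copies. None of the 3 calls was kept with each array left out: the count was 0 without WT replicate 1, 2 or 3 or ELL2 cko replicate 1, 2 without ELL2 cko replicate 2 and 29 without ELL2 cko replicate 3. With the 4 arrays left out 0 genes were called, with 1606 at an unadjusted limma p under 0.05, and 8 were called after a further quantile normalization.

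With LPS, genes of protein secretion were lower in ELL2 cko than in WT cells. Fkbp11 was 4.36 ± 0.53 log2 units lower (log2 difference -4.36, SE, n = 3 and 4, adjusted p = 3.97e-04), Edem1, which marks misfolded glycoproteins for degradation, fell by 3.36 ± 0.30 (adjusted p = 5.6e-05), and Xbp1 fell by 2.68 ± 0.27 (adjusted p = 1.35e-04). Prdm1 fell by 1.97 ± 0.34 (adjusted p = 0.0042). Irf4 fell by 1.58 ± 0.33 (adjusted p = 0.0129), a call that was lost without ELL2 cko LPS replicate 3 (adjusted p = 0.0567). Rgcc, a regulator of the cell cycle (-3.85 ± 0.41), the Golgi enzyme Qpctl (-3.65 ± 0.45), the Golgi trafficking factor Hid1 (-3.60 ± 0.55), Chac1, a glutathione-degrading enzyme of the stress response (-3.35 ± 0.38), and Edem3 (-3.34 ± 0.51) were among the largest falls. Saa3 (5.19 ± 0.85), Mpeg1, a pore-forming protein (4.28 ± 0.75), and the interferon-inducible Trim30c (3.98 ± 0.72) were among the largest rises. Fcrl5 (4.20), Ifi203 (3.75), Lrrk2 (3.39) and Ifi206 (3.39) also rose and Tmed6 fell (-3.65), with calls that were lost without ELL2 cko LPS replicate 2 or 3 (adjusted p up to 0.0833). With ELL2 cko LPS replicate 1 alone, the array of this group without a high T cell marker mean, the differences of Saa3, Mpeg1, Trim30c, Ifi203, Ifi206, Edem3 and Prdm1 were 3.76, 3.24, 2.09, 2.50, 2.11, -2.10 and -1.22. In replicate 1 the Ell2 exon region PSR1300005919.mm.1 was 11.38, against 7.97 and 7.87 in replicates 2 and 3. Fewer other cells and a higher level of this region thus cannot be told apart there. Tmed6 and Rgcc lay near the median gene in ELL2 cko with LPS, so their falls are read as lower limits. Iglc2, a lambda light chain constant region, fell by 1.10 ± 0.15. Ighm differed by -0.04 ± 0.11 (adjusted p = 0.917), Pax5 by 2.21 ± 0.79 (adjusted p = 0.147), Atf6 by -1.03 ± 0.34 (adjusted p = 0.108) and Tnfrsf17 by -0.65 ± 0.22 (adjusted p = 0.13).

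The antibody-secreting cell list was lower, with 22 of 31 members falling and none rising (25 over the list alone). The median difference was -1.97 (camera adjusted p = 4.77e-47, adjusted p = 0.0784 with an estimated correlation). The antibody-secreting list holds Ell2, the targeted gene, and shares Xbp1, Edem1, Derl3 and Creld2 with the unfolded protein response list. Of 39 unfolded protein response genes 26 fell (32 over the list alone), among them Sel1l (-3.28). The median difference was -1.90 (adjusted p = 9.12e-49, adjusted p = 0.0784 with an estimated correlation). Of 46 ER translocation and secretion genes 31 fell (38 over the list alone), among them the retrieval receptors Kdelr2 (-3.12) and Kdelr3 (-2.80, a lower limit since it lay below the median gene in ELL2 cko). Their median was -1.59 (adjusted p = 4.33e-40, adjusted p = 0.165 with an estimated correlation). The mean of the antibody-secreting list was 13.57, 12.42, 13.44 and 12.60 in the WT LPS arrays and 11.15, 10.86 and 10.93 in the ELL2 cko LPS arrays. Mature B cell identity genes rose in 7 of 32 cases (22 over the list alone, median 1.54, adjusted p = 3.71e-14, adjusted p = 0.331 with an estimated correlation). Their mean was 9.10, 11.54, 9.69 and 11.35 in WT LPS replicates 1 to 4 and 11.85, 12.06 and 12.18 in ELL2 cko LPS replicates 1 to 3. Among them were Fcrl1 (2.24 ± 0.45), whose call was lost without ELL2 cko LPS replicate 2 or 3 (adjusted p up to 0.0687), and Bcl11a (3.52 ± 0.87), lost without these or WT LPS replicate 1 or 3 (adjusted p up to 0.129). MHC class II genes rose in 3 of 14 cases (13 over the list alone, median 1.86, adjusted p = 1.85e-08, adjusted p = 0.337 with an estimated correlation). The MHC class II mean was 10.30, 12.94, 10.68 and 13.01 in the WT and 13.44, 13.51 and 13.61 in the ELL2 cko arrays, so the size of both differences depends on the WT array. Interferon response genes rose in 8 of 29 cases and fell in 2 (17 over the list alone, median 1.06, adjusted p = 1.13e-05, adjusted p = 0.386 with an estimated correlation). The mean of the T cell markers was 5.07, 6.70 and 6.88 in these ELL2 cko arrays, with a median difference of 0.98 from WT (adjusted p = 0.0421, adjusted p = 0.79 with an estimated correlation), and that of the monocyte markers 5.42, 6.20 and 6.15 (median difference 0.52, adjusted p = 0.0757). The T cell marker call was lost without ELL2 cko LPS replicate 2 or 3 or WT LPS replicate 1, 2 or 4 (adjusted p up to 0.168). Without the 4 arrays the medians of the antibody-secreting, unfolded protein response, ER and B cell identity lists were -1.76, -1.68, -1.59 and 1.33, that of the interferon list 0.11, and single members called numbered 2, 3, 0, 0 and 0, all from 1 ELL2 cko LPS array. The difference of Sel1l was -1.89 there.

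**Figure D2:**
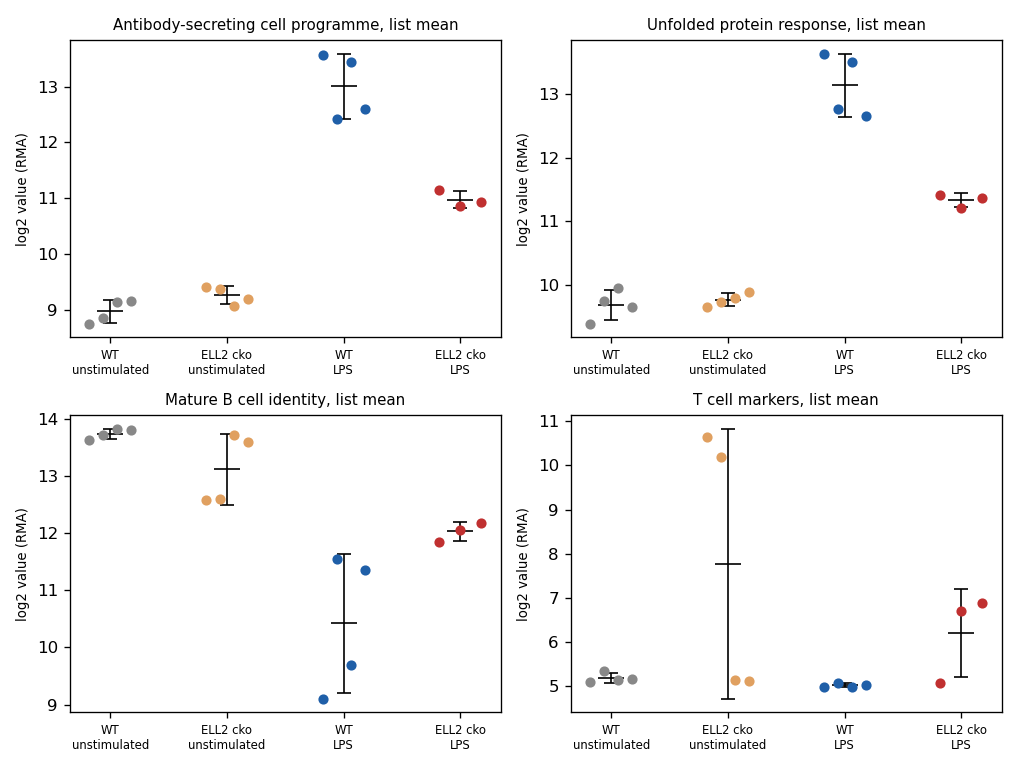
Mean log2 value per array of gene lists fixed before the data were examined, by group; each point is an array. The antibody-secreting cell list lies between 12.42 and 13.57 in WT LPS arrays and between 10.86 and 11.15 in ELL2 cko LPS arrays, and T cell markers reach 10.64 in ELL2 cko arrays against at most 5.34 in WT.

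Oxidative phosphorylation genes fell in 3 of 38 cases in ELL2 cko with LPS (9 over the list alone, median -0.41, camera adjusted p = 1.7e-04, adjusted p = 0.393 with an estimated correlation), led by Ndufa1 (-1.92 ± 0.29) and Uqcrq (-1.90 ± 0.34). Replication-dependent histone genes fell in 3 of 35 cases (9 over the list alone, median -0.46, adjusted p = 3.98e-05, adjusted p = 0.186 with an estimated correlation). Their mean was 8.06, 6.99 and 7.09 in ELL2 cko LPS replicates 1 to 3, against 7.95 to 8.42 in WT, and with replicate 1 alone the median was -0.24 and the list was not called. The cell cycle list had a median of -0.55 (adjusted p = 0.0014, adjusted p = 0.669 with an estimated correlation) with no member called, and its call was lost without ELL2 cko LPS replicate 2 (adjusted p = 0.0567). With replicate 1 alone of these arrays its median was -0.03 and the direction of its test turned, and it was not called with the T cell marker mean as a covariate. NF-kB target genes rose in 2 of 30 cases and fell in 1 (5 over the list alone, median 0.56, adjusted p = 0.002, adjusted p = 0.337 with an estimated correlation). The splicing regulator Mbnl2 fell by 2.24 ± 0.36 and the minor spliceosome RNA Rnu12 by 2.72 ± 0.39 (log2 difference -1.74 with replicate 1 alone). The lists of core spliceosome, SR and hnRNP, cleavage and polyadenylation and Integrator genes were not called (medians 0.03, 0.01, 0.02 and 0.01, adjusted p = 0.842, 0.951, 0.895 and 0.903).

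In total 1462 genes differed between genotypes with LPS, 428 higher and 1034 lower, with 1124 differing by at least 1 log2 unit. The share of higher genes was 29.3%, and 43.6% of 1712 called genes after a further quantile normalization. Without the 4 arrays, which leaves 1 ELL2 cko LPS array (replicate 1) against 4 of WT and takes the spread from the other groups, 35 genes were called, all lower, 34 of them also called with all arrays. In that fit 3393 genes had an unadjusted p under 0.05. The count was 863 without WT LPS replicate 1, 724 without WT LPS replicate 3, 556 without ELL2 cko LPS replicate 2 and 590 without ELL2 cko LPS replicate 3, 444 when only the 2 groups were fitted, and 927 with the sex of the mouse as a term. Of 62 named genes called, 24 kept their call with any 1 array left out, and 3 kept it with the single ELL2 cko LPS array: Rgcc, Edem1 and Ctla4 (-3.56, -2.70 and -2.24 there). The differences of Fkbp11, Xbp1, Irf4 and Prdm1, whose calls were lost, were -4.31, -2.55, -1.76 and -1.22 in that fit.

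The LPS response itself differed between genotypes for 428 genes, 58 with a more positive and 370 with a more negative change in ELL2 cko. Over all arrays large differences of log2 changes, ELL2 cko minus WT, included those of Fkbp11 (-4.96 ± 0.73, SE, adjusted p = 0.0074), Ctla4 (-4.43 ± 0.76, adjusted p = 0.0125), Rgcc (-4.30 ± 0.56, adjusted p = 0.0057), Hid1 (-4.21 ± 0.75, adjusted p = 0.0145), the purine enzyme Ada (-3.85 ± 0.58, adjusted p = 0.0077) and Creb3l2, a transcription factor of secretory cells (-3.66 ± 0.70, adjusted p = 0.0215). Fkbp11 and Ctla4 lay near the median gene in WT without LPS, and Rgcc in ELL2 cko with LPS. The sizes of their differences are thus not exact and not ranked. Xbp1 differed by -2.62 ± 0.37 (adjusted p = 0.0072) and Prdm1 by -2.08 ± 0.46 (adjusted p = 0.0439). The Prdm1 call was lost on leaving out any 1 of 12 of the 15 arrays (adjusted p up to 0.142). That of Ctla4 was lost without ELL2 cko LPS replicate 2 (0.0544), that of Hid1 without replicate 2 or 3 (up to 0.0579) and that of Creb3l2 without these or WT unstimulated replicate 1 (up to 0.0896). Ctla4 was 7.36, 6.96, 4.98 and 4.65 in ELL2 cko replicates 1 to 4 without LPS, against 4.47 to 4.88 in WT, and without the 4 arrays its difference of changes was -2.46. Those of Fkbp11, Rgcc, Hid1, Ada, Creb3l2 and Prdm1 were then -4.69, -3.42, -3.09, -4.44, -3.01 and -1.26. Ell2 (-1.61 ± 0.40, adjusted p = 0.0681), Irf4 (-1.24 ± 0.45, adjusted p = 0.225) and Pax5 (2.89 ± 1.07, adjusted p = 0.243) were not called.

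Antibody-secreting genes had a more negative change in ELL2 cko in 15 of 31 cases (28 over the list alone, median -2.23, camera adjusted p = 2.63e-40, adjusted p = 0.0784 with an estimated correlation). The same held for 15 of 39 unfolded protein response genes (26 over the list alone, median -1.90, adjusted p = 1.99e-39, adjusted p = 0.0784 with an estimated correlation) and 13 of 46 ER genes (36 over the list alone, median -1.64, adjusted p = 2.83e-32, adjusted p = 0.186 with an estimated correlation). Mature B cell identity genes had a more positive change in 3 of 32 cases (23 over the list alone, median 2.20, adjusted p = 6.49e-22, adjusted p = 0.191 with an estimated correlation). The MHC class II list had a median of 2.36 (12 over the list alone, adjusted p = 2.48e-09, adjusted p = 0.331 with an estimated correlation) and the cell cycle list one of -1.10 (11 over the list alone, adjusted p = 1.85e-11, adjusted p = 0.378 with an estimated correlation), with no member called over all genes. Beside these groups, NK cell, monocyte and neutrophil markers differed by medians of -1.48, -1.11 and -2.42 (adjusted p = 0.002, 9.77e-04 and 0.0038, or 0.622, 0.651 and 0.678 with an estimated correlation). The neutrophil call was lost without ELL2 cko unstimulated replicate 1 or 2 (adjusted p up to 0.0853). Without the 4 arrays the medians of the B cell identity, MHC class II, NK cell, monocyte and neutrophil lists were 1.53, 1.56, 0.05, -0.15 and 0.16.

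Across 31366 genes, which are not independent replicates, the LPS changes of the 2 genotypes correlated with Pearson's r = 0.754 and Spearman's rho = 0.618, and the major axis had a slope of 0.582. The 2 changes shared no arrays. Of the 7671 genes called with LPS in WT, 76.1% differed between genotypes with LPS in the direction opposite to their LPS change, when separate WT LPS arrays gave the change and the difference. With no genotype difference, 20 simulations gave a mean of 57.2% and a highest value of 58.0%. The simulated genes varied independently, while genes of the WT LPS arrays moved together (B cell identity means of 9.10, 11.54, 9.69 and 11.35). The simulated range is thus too narrow to set against 76.1%, and whether chance gives such a share is not decided. The interaction count by limma without the 4 arrays was 0, with 3080 genes at an unadjusted p under 0.05, but with 1 ELL2 cko LPS array and 2 unstimulated ones left this says little about the interaction. The interaction count was 109 without ELL2 cko LPS replicate 2, 124 without replicate 3, 707 without replicate 1, 248 without ELL2 cko unstimulated replicate 1, 179, 176 and 212 without WT unstimulated replicates 1, 2 and 3, and 247, 1072 and 196 without WT LPS replicates 1, 2 and 3. The share of more positive changes was 13.6%, and 31.4% of 379 called genes after a further quantile normalization.

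**Figure D3:**
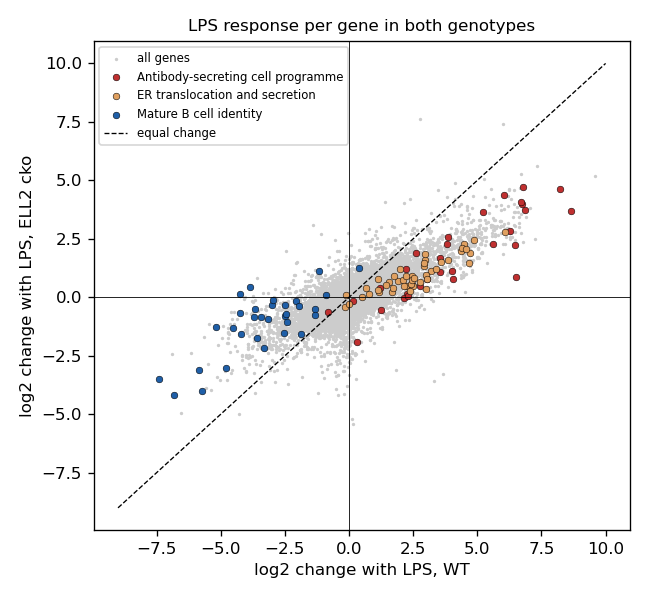
Log2 change with LPS in ELL2 cko (vertical axis) against that in WT (horizontal axis) for each of the 31366 genes, with members of the antibody-secreting, ER and B cell identity lists coloured and a dashed line of equal change. Over all genes the major axis has a slope of 0.582.

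Exon regions and junctions within a gene were called as changing unequally with LPS in many genes, the immunoglobulin mu heavy chain gene Ighm among them. One Ighm exon region, PSR1200017565.mm.1, was 10.10 ± 0.12 (SD, n = 4) in WT cells without LPS and 13.66 ± 0.52 (n = 4) with LPS, and 9.43 ± 0.46 (n = 4) and 10.29 ± 0.81 (n = 3) in ELL2 cko cells. It rose by 3.57 with LPS in WT while the median change of the gene's tested exon regions and junctions was 0.06, and it differed by -3.38 between genotypes with LPS. The gene was called in WT (diffSplice adjusted p = 4.76e-30, splicing index adjusted p = 4.89e-05) and between genotypes with LPS (1.55e-26 and 0.0032). Other Ighm regions lie near the ceiling of the scale, where a change is hardly visible. The calls for Ighm thus do not show that this region moved apart from those regions. Some junctions of the gene lay below the ceiling. JUC1200010355.mm.1 had means of 7.79 and 8.33 in WT without and with LPS, and 8.76 in ELL2 cko with LPS. JUC1200010356.mm.1 had 12.34, 13.49 and 13.78. Unlike the exon region, neither mean was lower in ELL2 cko than in WT with LPS. Against these junctions the region moved apart. The part of the gene that this region covers is not given in the sources used here. Ell2 itself was called between genotypes with LPS (1.08e-19, splicing index 6.78e-04), its exon region PSR1300005919.mm.1 falling by 6.75 relative to the rest of the gene. In Ptprc, which encodes the phosphatase CD45 with its variable exons, 72 of 79 rows fell and 2 rose with LPS in WT. The rows that rose were exon region PSR0100025711.mm.1 (2.43, adjusted p = 0.00177) and junction JUC0100014630.mm.1 (2.24, adjusted p = 0.00623), while the median change of its rows was -1.37 (gene adjusted p = 6.69e-22, splicing index 8.95e-05). An exon region of the phosphatase gene Dusp14 rose by 9.64 with LPS in WT against a median of 1.63 for the rows of the gene (splicing index adjusted p = 2e-07). A junction of Ikzf1, the lymphoid transcription factor Ikaros, rose by 4.72 against -0.04 (4.47e-06), one of Fryl by 4.98 against -0.56 (2.36e-04) and one of the formin Fmnl1 by 3.54 against -1.74 (1.54e-04). In the amino acid transporter gene Slc7a3 a junction rose by 11.74 in WT and 9.48 in ELL2 cko, more than the medians of its rows, 6.56 and 4.24.

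Unequal change was called for 7285 of 10741 genes with LPS in WT (6953 by the splicing index, 6160 by both), 3129 of 10991 with LPS in ELL2 cko (1651), 445 of 10996 between genotypes without LPS (1), 2325 of 11011 with LPS (501) and 663 of 10540 for the difference of responses (0). The splicing index, the value of a row minus the median of its gene with its own variance, was added after seeing the data, because on simulated data for LPS in WT the first test called 747 unchanged genes when 200 of 10741 were changed by 2 log2 units and the index called 2. Of the genes called by the first test, 1880, 199, 0, 61 and 0 in these comparisons had at least 1 row rising and 1 falling. Each such row had a limma adjusted p under 0.05 and a change of at least 1 log2 unit. Rows near either end of the scale can change less than other rows of a gene whose level changes. The counts of unequal change are thus not counts of genes with changed splicing. In WT with LPS, called genes included 45 of 51 SR and hnRNP regulators (42 by the index) and 35 of 37 ribosomal protein genes (30). Between genotypes with LPS they included 18 of 30 antibody-secreting genes (14), 19 of 38 unfolded protein response genes (11) and 22 of 51 SR and hnRNP regulators (5). With the 4 arrays left out the first test called 1578, 238, 869 and 573 genes in the last 4 comparisons, and the index 155, 1, 1 and 0. The counts by the first test were 1615 and 1824 without ELL2 cko LPS replicates 2 and 3 for LPS in ELL2 cko, and 4145, 958, 1213 and 1325 without ELL2 cko LPS replicates 1, 2 and 3 and WT LPS replicate 3 between genotypes with LPS. Between genotypes without LPS they were 190, 172, 1020 and 858 without ELL2 cko replicates 1 to 4 and 206, 247 and 289 without WT replicates 2 to 4. For the difference of responses they were 1203 and 430 without ELL2 cko LPS replicates 1 and 2, and 1115 and 356 without WT LPS replicates 2 and 3.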

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

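Of the tests in this part, only that of the small nucleolar RNA genes was written before its result was seen, and the others, including all splits of the arrays, were chosen after.

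In 7 of 201 tests for 1 array lying far from the others of its group, a gene that the report names stood out, with about 1 in 20 such tests passing by chance. These were Ctla4 in WT unstimulated replicate 3 (4.88), Cd55 in WT unstimulated replicate 1 (17.33), Ell2 in WT unstimulated replicate 2 (10.87), Ighe in WT LPS replicate 2 (7.01), Ighg2b in WT unstimulated replicate 4 (11.83), Atf6 in WT LPS replicate 4 (14.39) and Txn1 in WT LPS replicate 4 (14.33). No cause was tested for these values. Only groups of 4 arrays entered these tests, so the ELL2 cko LPS group with 3 arrays was not examined. There the T cell marker mean was 5.07 in replicate 1, against 6.70 and 6.88 in replicates 2 and 3.

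The LPS response differed between genotypes, by a test of the difference itself, for 428 genes. Among the named ones the differences of log2 changes, ELL2 cko minus WT, were -4.96 for Fkbp11, -4.43 for Ctla4, -4.30 for Rgcc, -4.21 for Hid1, -3.85 for Ada, -3.66 for Creb3l2, -2.08 for Prdm1 and -2.62 for Xbp1.

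Markers of T, NK, myeloid and neutrophil cells were high in ELL2 cko unstimulated replicates 1 and 2. These arrays were picked by their T cell marker mean, so that list says nothing further. Of the 49 members of the NK cell, monocyte and neutrophil lists, which were not used to pick them, 98% lay above the highest WT unstimulated array in both arrays, as RNA of such cells would give. The genotype as the only cause cannot be judged from these arrays. All 7 ELL2 cko arrays were low in the Ell2 exon region, and 4 of them had a high T cell marker mean. These 4 were also lowest in that region, with 8.98 and 7.96 without LPS and 7.97 and 7.87 with LPS. The others had 10.06 and 9.35 without LPS and 11.38 with LPS. The Ell2 junction JUC1300003129.mm.1 had the same order with LPS (9.65, 7.06 and 7.74 in replicates 1 to 3). Without LPS it had 8.58, 7.88, 7.25 and 7.64 in replicates 1 to 4, so replicates 1 and 2 were not lowest there. With LPS the degree of Ell2 loss and the markers thus cannot be told apart. Without LPS the rows disagree on which arrays lost most. Whether purification or the animals differed was not tested.

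Secretory and unfolded protein response genes were lower in ELL2 cko with LPS. Dilution by RNA of other cells as the only cause is argued against, because the median of the mature B cell identity list was 1.54 higher. That list itself fell with LPS in WT (median -3.24), so a weaker LPS response could hide dilution. Dilution as a part of the difference is thus not excluded. The antibody-secreting list means did not overlap (12.42 to 13.57 in 4 WT arrays, 10.86 to 11.15 in 3 ELL2 cko arrays), and limma called 22 of its 31 members. Ell2, the targeted gene, was among these members. Differences from culture to culture still cannot be told apart from the genotype. The exact permutation p of the list means was 0.0571, the smallest possible two-sided value with 3 and 4 arrays, so that test could not pass and decides nothing. The labels do not say whether the genotypes were cultured together. Less ELL2, the biological explanation that the design names, stays open beside it.

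Small nuclear RNA genes were higher in ELL2 cko without LPS. More short RNA in the extract is argued against for 75 small nucleolar RNA genes outside the list, whose median difference was -0.05 (quartiles -0.29 and 0.36). The list itself holds other small nucleolar RNA genes, such as Rnu3a, so the test does not cover every short RNA. The genotype in all arrays is argued against, since the median of the list without the 4 arrays was 4e-04. RNA of other cells stays open: with the T cell marker mean as a covariate the list was no longer called, but that mean was high in the same 2 arrays. Those 2 were also the unstimulated arrays lowest in the Ell2 exon region, but not in the Ell2 junction JUC1300003129.mm.1. Whether the degree of Ell2 loss plays a part beside other cells is thus not decided.

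Whether chance alone gives counts as large was tested by splitting the same arrays into groups in other ways. For genes called, the real grouping of LPS in WT gave 7671 and was the 1 split as large among 35 (highest other 1), that of LPS in ELL2 cko gave 3246 and was 1 of 35 (536), that of genotype without LPS gave 4 and was 1 of 35 (3), and that of the difference of responses gave 428 and was 1 of 100 (370). For LPS in WT and in ELL2 cko the real count lay far above that of every other split. Each other split mixes arrays with and without LPS, which adds the LPS change to the spread. With many such tests and 1 of 35 as the smallest possible share, the splits do not exclude chance. For the other 2 the real grouping also gave the highest count, and chance is not excluded there either. For the difference of responses the count with 1 array left out was 109 to 1072. For genotype without LPS it exceeded another split by 1 gene, and the count was 0 with a replicate block, dim genes filtered, arrays centred, trend and robust settings or only the 2 groups. For genotype with LPS the count was 1462, with 2 of 35 splits as large (highest other 1742), and chance cannot be excluded for the count. For lists called, adjusted within the comparison, the values were 14 (3 of 35 as large, highest other 17) for LPS in WT, 22 (2 of 35, 22) for LPS in ELL2 cko, 11 (15 of 35, 20) and 10 (9 of 35, 13) for genotype without and with LPS, and 13 (36 of 100, 21) for the difference of responses. Chance cannot be excluded for any of these list counts. For unequal change within genes LPS in WT gave the highest count (7285, 1 of 35, highest other 1341), with the same limit. At least 1 other split was as large for LPS in ELL2 cko (3129, 3 of 35, 4207), genotype without LPS (445, 6 of 35, 2101), genotype with LPS (2325, 2 of 35, 3065) and the difference of responses (663, 10 of 40, 2301). Chance cannot be excluded for these counts.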

How the results depend on the processing

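Leaving out the 4 arrays with markers of other cells, the T cell marker mean as covariate, sex, the splicing index and genes with rows that rise and fall were chosen after seeing the data. Leaving out the 4 arrays keeps 1 ELL2 cko array with LPS and 2 without, so a call lost there says little. The arrays left out were also the ELL2 cko arrays lowest in the Ell2 exon region, though not in its junction JUC1300003129.mm.1 without LPS. A move in that fit thus need not come from other cells. The cause of each move given here was not tested, except that a size threshold lowers a count by construction. Leaving out an array moved counts both ways. Between genotypes with LPS 1462 genes became 2162 without WT LPS replicate 2 and 556 without ELL2 cko LPS replicate 2. Signal over background, with background rows at 3.02 to 3.43, limits calls among dim genes, and the number of arrays limits all.

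Genes called with LPS in WT kept a count of 6488 to 7744 with 1 array left out, and 4114 changed by at least 1 log2 unit. With LPS in ELL2 cko the count was 1931 to 3148 with 1 array left out, 2156 with only the 2 groups fitted, 1306 without the 4 arrays and 1855 at the size threshold. Between genotypes without LPS it was 0 to 29 with 1 array left out, 0 with dim genes filtered, 8 after a further quantile normalization, 0 with arrays centred, 0 with trend and robust settings, 0 with only the 2 groups, 0 without the 4 arrays, 9 with the T cell covariate and 0 with sex as a term. Between genotypes with LPS it was 556 to 2162 with 1 array left out, 444 with only the 2 groups, 35 without the 4 arrays and 927 with sex. For the difference of responses it was 109 to 1072 with 1 array left out, 0 without the 4 arrays, 798 with the T cell covariate and 276 with sex.

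Genes with unequal change numbered, for the 5 comparisons in the same order, 14123, 6141, 1332, 4762 and 1905 without a filter on level, and 1880, 199, 0, 61 and 0 with rows that rise and fall (1830, 154, 0, 35 and 0 by the splicing index). In the last 4 comparisons the splicing index gave 1651, 1, 501 and 0, and without the 4 arrays 155, 1, 1 and 0, while the first test without the 4 arrays gave 1578, 238, 869 and 573. Without junctions the last 3 counts were 194, 1163 and 228, and the F test gave 276 between genotypes without LPS. With 1 array left out the counts were 6391 to 7544, 1615 to 4215, 172 to 1020, 958 to 4145 and 356 to 1203.

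Of 160 list tests 71 were called, 66 to 75 with 1 array left out, 58 to 78 under the other alternatives with the preset correlation, and 0 with an estimated correlation. Without the 4 arrays the median turned for immediate early genes (0.12), neutrophil markers (0.20) and small nuclear RNA genes (0.69) with LPS in ELL2 cko, and that of T cell markers there went from -1.63 to 0.01. The same held for cleavage and polyadenylation (0.04), T cell (-0.10) and neutrophil (-0.09) lists between genotypes without LPS, and for NK cell (0.05) and neutrophil (0.16) markers in the difference of responses. Between genotypes with LPS the T cell list was -0.05 without the 4 arrays, and the cell cycle list -0.03, its test direction turning. With the T cell covariate the small nuclear RNA list with LPS in ELL2 cko was 0.10, the cleavage list 0 and the T cell list -0.05 between genotypes without LPS, and the T cell list -0.09 with LPS. Iglc3 with LPS in WT was -0.25 after a further quantile normalization, and Txnl4a with LPS in ELL2 cko was 0.15 with the mean of exon regions. With the 4 arrays left out, of 92, 82, 3, 62 and 8 named genes called in the 5 comparisons, 91, 46, 0, 3 and 0 kept their call.

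The correlation of LPS changes was 0.698 to 0.778 with 1 array left out and 0.78 with dim genes filtered. The share of genes moved back was 73.0% to 77.4% with 1 array left out and 82.2% at the size threshold. The Ell2 difference with LPS was -2.29 to -1.92 for Ell2 level with 1 array left out, -2.12 without the 4 arrays, where it no longer passed, and -0.07 for the lowest row of the gene, which lay at 2.10 to 2.45, below the background rows, and cannot show a difference.

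Arrays share replicate numbers, but the deviations of arrays with the same number from their group means correlated by -0.28 to 0.25, so the number was not taken as a pairing. Across numbers, ELL2 cko unstimulated replicates 3 and 4 correlated with LPS replicate 1 by 0.34 and 0.29. Unstimulated replicates 1 and 2 correlated with LPS replicates 2 and 3 by 0.20 to 0.25, and with LPS replicate 1 by -0.28 and -0.32. These sets match the split by T cell markers. Whether a batch lies behind them was not tested. With a replicate block 7536, 3010, 0, 1400 and 346 genes were called, 7304, 2958, 437, 1995 and 647 genes had unequal change, 72 lists were called, the correlation was 0.728 and the Ell2 difference -2.09.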

Other observations

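The germinal centre list and the B1 and marginal zone list moved little as wholes with LPS in WT, while single members changed. Bcl6, the master regulator of germinal centre B cells, fell by 2.52 ± 0.39 (log2 change ± SE, n = 4 and 4) with LPS in WT, and Exo1, a DNA repair exonuclease, rose by 2.16 ± 0.32. The germinal centre list itself was not called (median 0.05, limma camera adjusted p = 0.813, 4 of 16 higher and 4 lower). In the marginal zone and B1 list 8 of 18 rose and 5 fell (median -0.03, adjusted p = 0.988). Its rises included those of Ctla4 (a lower limit), Mzb1 and Zbtb32, which plasma cells also express. Of 27 elongation factors 5 rose and 3 fell with LPS in WT (median 0.13, adjusted p = 0.439), among them the ELL partner Eaf2 (6.74 ± 0.54) and Ell3 (-2.15 ± 0.19, to a level near the median gene). NF-kB targets rose in 8 of 30 cases and fell in 7 (median 0.02, adjusted p = 0.833), with Il10 up by 6.22 ± 0.70, a lower limit since it lay below the median gene without LPS (3.80 to 4.98), and Cd40 down (-3.31 ± 0.67). Apoptosis regulators rose in 8 of 19 cases and fell in 1 (12 over the list alone, median 0.52, adjusted p = 0.0076, adjusted p = 0.186 with an estimated correlation), among them the survival factor Bcl2l1 (3.12, from a level near the median gene) and the killer Bcl2l11 (3.47). Ribosomal protein genes rose in 19 of 49 cases and fell in 5 (median 0.18, adjusted p = 0.186).

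Further lists with LPS in WT were not called: core spliceosome (median -0.06, 5 of 51 higher and 4 lower), cleavage and polyadenylation (-0.03, 3 and 6 of 28), Integrator (0.08, 2 and 2 of 16), immunoglobulin constant regions (0.31, 4 and 1 of 10), immediate early genes (0.26, 3 and 3 of 24), small nuclear RNA genes (1.40, 8 and 2 of 18), dendritic cell (-0.14, 2 and 2 of 12), erythroid (-0.09, 0 and 0 of 6) and stromal and endothelial markers (-0.06, 1 and 1 of 14). Their adjusted p-values were 0.642, 0.245, 0.898, 0.364, 0.903, 0.133, 0.886, 0.742 and 0.492. The small nuclear RNA list was called with LPS in WT when the 4 ELL2 cko arrays with markers of other cells were left out or the T cell marker mean was a covariate. None of these arrays is in this comparison, but they add to the spread shared by the groups. Bst2, counted among dendritic markers, also belongs to the interferon list. Platelet markers fell in 4 of 9 cases (4 over the list alone, median -0.61, adjusted p = 0.0428, adjusted p = 0.339 with an estimated correlation), a list call lost without WT LPS replicate 1 or 2 or WT unstimulated replicate 1 (adjusted p up to 0.0881). With LPS in ELL2 cko, SR and hnRNP regulators fell in 9 of 54 cases and rose in 2 (14 over the list alone, median -0.23, adjusted p = 0.0012, adjusted p = 0.186 with an estimated correlation), with Srsf5 down by 2.16 ± 0.32. Histone genes rose in 6 of 35 cases (7 over the list alone, median 0.64, adjusted p = 4.36e-04, adjusted p = 0.212 with an estimated correlation), a list call lost without ELL2 cko LPS replicate 1 (adjusted p = 0.0772). In the difference of LPS responses, ELL2 cko minus WT, small nuclear RNA genes had a median of -1.99 (adjusted p = 9.69e-07, adjusted p = 0.378 with an estimated correlation), oxidative phosphorylation genes -0.58 (1.3e-07 and 0.331) and histone genes -0.63 (9.29e-06 and 0.186). Without the 4 arrays with markers of other cells these medians were -0.34, -0.79 and -0.28, and that of histone genes with LPS in ELL2 cko 1.13.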
